A study of Mus musculus with 6 samples.

How the data were processed

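Accessible chromatin was profiled by ATAC-seq (assay for transposase-accessible chromatin with sequencing) in mouse epididymal white adipose tissue. The series holds 6 libraries, 3 from flox controls, whose Armc5 alleles carry recombination sites but are not deleted, and 3 from mice with Armc5 deleted in adipocytes (Armc5 KO). Per the labels' protocols, DNA was extracted and libraries were made with a commercial ATAC-seq kit from Active Motif. The labels do not say whether the samples of a group came from separate mice, so p-values measure the spread between these samples, which may be technical.

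Per the submitters' processing notes, cutadapt 4.0, Bowtie2 2.3.5.1, deepTools 3.5.1 and MACS2 2.2.7.1 were used with the mm10 genome build. The notes give these names with no role or order. Whether insertion sites were shifted, duplicates or mitochondrial reads removed, or a list of excluded regions applied is not given in the sources used here. The deposited table lists 104 intervals, each a stretch in which peaks of 1 or more libraries were joined. Per the file headers, the authors gave, for each library, whether a peak was called, its start, end and summit, its fold enrichment over background, and the −log10 of its p-value and q-value. Peaks were therefore called per library, not on pooled reads. The deposited fold is a ratio set by the authors' peak caller within each library and was not normalized between libraries. Per the file headers, each interval also carries an annotation with a transcript, a distance to the nearest transcription start site and a gene name. The name is that of a nearby start site, which can lie outside the interval. Columns headed WT were read as flox control, since the titles name only flox and KO samples with the same replicate numbers. Interval starts were assumed to be counted from 0 in the table and are printed counted from 1.

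The table gives no counts and no read totals. The fold and the −log10 p of each peak were solved for a whole fragment pileup at the summit (the number of fragments over that base) and a local background, taking the fold as (pileup + 1)/(background + 1) and the p-value as a Poisson tail. All 519 peaks matched a whole pileup within 0.005 of the deposited −log10 p, 514 of them with no second whole number inside that tolerance. In a test on 500 simulated peaks the pileup was recovered for 100% and a whole number matched an unrelated p-value for 2.2%. The libraries' median pileup over the 55 intervals called in all 6 ranged from 56 to 90 fragments, and this stands in for depth, which is otherwise unknown. Where a library had several peaks in an interval, the peak with the highest fold was used.

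Pileups of Armc5 KO 1 and 2 over the 55 intervals did not differ beyond sampling noise (chi-square per degree of freedom 0.881), nor did those of Armc5 KO 1 and 3 (1.04). A pair from different groups, flox control 1 and Armc5 KO 1, was nearly as close (1.12), so these libraries were kept as separate samples, and averaging Armc5 KO 1 and 2 as 1 sample was tried as an alternative.

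The number of intervals per library and the share of each annotation class were compared with exact two-sided permutation tests, for which 3 against 3 samples allow no p under 0.1. Shares of intervals carry exact Clopper-Pearson 95% intervals. Groups were said to share an interval when at least 1 library of each had a peak in it. Fold enrichment was compared with limma 3.58.1 (moderated test with a trend, R 4.3.3) on log2(fold + 1) over the 55 intervals called in all 6 libraries. A difference on this scale understates that of low folds. The filter on a mean fold above 1 removed none of them. P-values were adjusted with the Benjamini-Hochberg method at 0.05. On simulated data with the spread of these 55 intervals, this test made 0.62 false calls per simulation. It recovered 44.6% of intervals given a log2 change of 0.5, 80% of those given 1 and 98.8% of those given 2. Each simulation changed 5 intervals at each size at once, which makes the adjusted threshold easier to pass. Recovery of a lone change was not simulated and would be lower. Errors were drawn independently for each interval, with the same spread in both groups. Real libraries can share errors across intervals and differ in spread, so these rates may not hold for them. Since the values were no counts, the count test set out for this comparison was replaced by its stated alternative for normalized values.

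Genes were named by a rule set before the data were examined. It takes Armc5, then Srebf1, Srebf2, Scap, Scd1 to Scd4, Fasn, Acaca, Acly, Elovl6, Fads1, Fads2, Pparg, Cebpa and Adipoq, intervals past the adjusted threshold, the 10 most enriched intervals of each group with 1 per gene, up to 10 of the most enriched intervals found in 1 group only, and members of fixed gene lists that have an interval. There were 17 lists for lipid metabolism, ARMC5 partners, adipocytes and other cell types of the tissue. List counts were compared with those of 21883 protein-coding genes of the GRCm38.p6 reference, the assembly of mm10, with Fisher's exact test and Benjamini-Hochberg adjustment. Of the 67 gene names in the table, 38 were in that reference. No gene set test with a correlation between members was run, because no list member had an interval.

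Alternatives set before the data were examined were the pseudocount, the low-value filter, a stricter q-value, the most enriched intervals alone, reciprocal overlap, 1 interval per gene, within-gene intervals, the reference as background, the replicate number as a block, and, for the number of intervals and the limma comparison, each replicate left out. Others were added after seeing the data: the local ratio of pileup to background, median-centred pileup and fold, intervals with nearby summits, a common minimum peak width, peaks in place of intervals, presence in at least 2 libraries, averaged Armc5 KO 1 and 2, each replicate left out for shared intervals, annotation classes and the fold of the most enriched intervals, and list genes within 100 kb of an interval. No genome sequence, repeat annotation or list of excluded regions was used here. The work was done with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.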

Results

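ARMC5 is a substrate adaptor of a cullin 3 ubiquitin ligase, and the title of the series ties it to SREBF1, a transcription factor of lipid synthesis, and to fatty acid desaturation in adipocytes. Epididymal white adipose tissue of 3 flox controls and 3 adipocyte-specific Armc5 KO samples was profiled by ATAC-seq to compare chromatin accessibility. The deletion targets adipocytes, while the tissue also holds other cell types, so a change in adipocytes alone could be diluted. The 6 libraries together held 519 peaks, which the authors joined into 104 intervals (mm10) with 67 gene names. The intervals lay on all 19 autosomes, and 0 lay on chromosome X or Y. Their median width was 227 bp, from 89 to 1846 bp. Of the 104 intervals, 55 were called in all 6 libraries, 17 in 5, 14 in 4, 4 in 3, 6 in 2 and 8 in 1. Fold enrichment is the authors' own value per peak and ranged from 1.93 to 103 (102.589 in flox control 2). Median summit pileup over the 55 common intervals was 85, 90 and 58 fragments in flox controls 1, 2 and 3, and 56, 74 and 56 fragments in Armc5 KO 1, 2 and 3.

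Armc5 itself, on chromosome 7 from 128237357 to 128245100, had no interval in any library, and the nearest interval was 116 Mb away, so the deletion could not be checked from the called peaks. The same held for the lipid genes that the study concerns. Scd1, which encodes the stearoyl-CoA desaturase of adipose tissue, lay 1.24 Mb from the nearest interval, an interval in intron 1 of Fbxw4. Srebf1 lay 6.06 Mb, Srebf2 7.06 Mb, Fasn (fatty acid synthase) 11.8 Mb, Acly 8.48 Mb, Acaca 24.6 Mb and Elovl6 (a fatty acid elongase) 121 Mb from the nearest interval. Scd2, Scd3 and Scd4 lay 1.34, 1.41 and 1.30 Mb away, and Fads1 and Fads2, which encode the delta-5 and delta-6 desaturases, 35.5 Mb. The adipocyte regulators Pparg and Cebpa lay 11.7 and 23.1 Mb, and the adiponectin gene Adipoq 12.002 Mb, from the nearest interval. Of the 17 genes fixed in advance, Scap, which encodes the escort protein of the SREBPs, was the closest, 0.052 Mb from the Mir6236 interval on chromosome 9 (110281250 to 110281355). That interval was called in 4 libraries, with a fold enrichment of 38.6 ± 3.24 in flox controls 1 and 2 and 31.9 ± 1.22 in Armc5 KO 1 and 2 (SD, n = 2 each), a difference that was not tested because the interval was not called in every library.

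**Figure D1:**
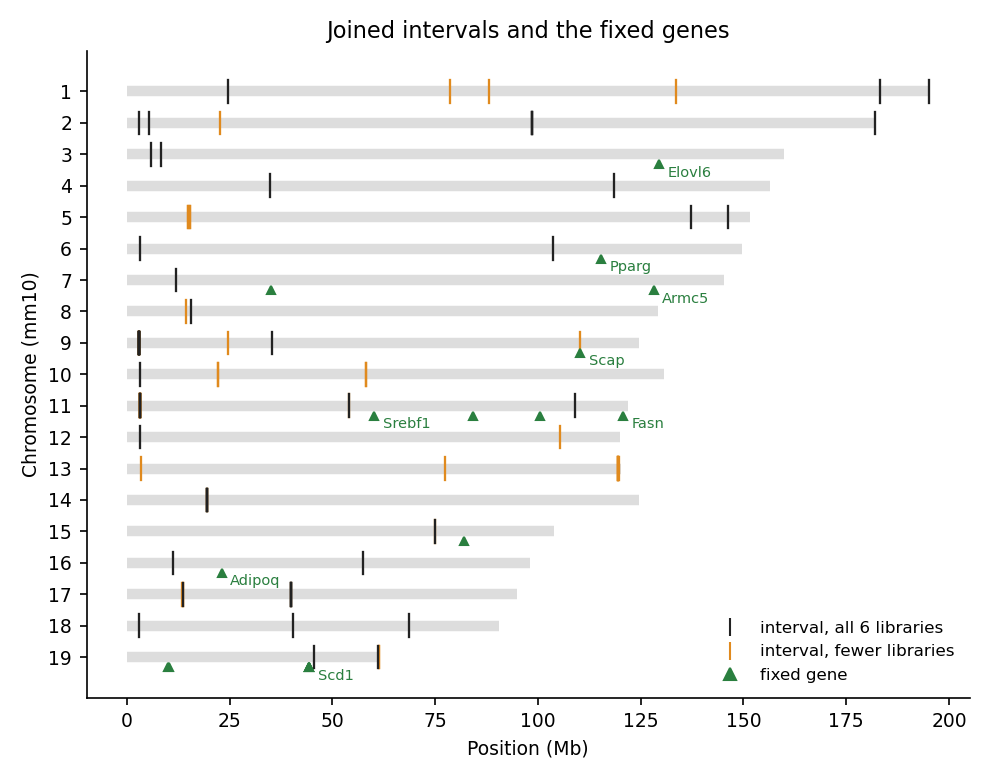
Positions (Mb, x axis) of the 104 joined intervals on the 19 autosomes (y axis, mm10), as black ticks where all 6 libraries had a peak and orange ticks where fewer did, with the 17 fixed genes as green triangles, 8 of them named; grey bars run from position 0 to the end of the last reference gene. No tick coincides with a fixed gene, and the closest, Scap, lies 0.052 Mb from one.

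No member of any of the 17 gene lists was named by an interval, 0 of 299 genes with a reference locus. By list, this was 0 of 27 genes for SREBP1 lipogenesis, 0 of 22 for fatty acid desaturation and elongation, 0 of 29 for cholesterol synthesis and uptake, and 0 of 10 for ARMC5 and the CUL3 ligase. It was 0 of 25 for adipocyte identity, 0 of 22 for lipolysis and fatty acid oxidation, and 0 of 20 for insulin and glucose handling. Markers of other cells gave 0 of 24 for macrophages and monocytes, 0 of 21 for lymphocytes, 0 of 13 for granulocytes and mast cells, 0 of 14 for endothelium, 0 of 19 for fibroblasts and adipocyte progenitors, 0 of 10 for pericytes and smooth muscle, 0 of 15 for mesothelium and epididymal epithelium, and 0 of 10 for skeletal muscle. The circadian clock list gave 0 of 14 genes, and the AP-1 and stress response list 0 of 15. Only 15 of 21883 protein-coding reference genes were named by an interval, so 0.205 list genes would be named at the reference share, and Fisher's exact test gave an adjusted p of 1.0 for each list. Within 100 kb, a distance chosen after the data were seen, lay 6 list genes: Acsl3, Scap, Hmgcs1, Ly6g, Tie1 and Ly6a. They were 2.01% of the 299 list genes, against 0.612% of protein-coding reference genes (Fisher's exact p = 0.0104 for all lists together). This test takes genes as independent, while Ly6g and Ly6a both lay near intervals named for Gm28502. No single list passed adjustment, the smallest adjusted p being 0.231.

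The most enriched intervals were mostly named for predicted genes and small RNA genes, by nearby start sites, while the reference places several of them in other genes or in none. The highest was at Gm10222, on chromosome 1 from 24612639 to 24612858, annotated to the promoter of an unprocessed pseudogene. Its fold enrichment was 91.7 ± 14.3 in flox controls and 88.8 ± 5.42 in Armc5 KO (SD, n = 3 each). An interval named for Gm44436, in intron 3 of a protein-coding transcript on chromosome 6 (103649092 to 103649287) and within Chl1 in the reference, reached 82.8 ± 1.096 and 82.2 ± 4.28. An intergenic interval near Gm9075 on chromosome 12 (3109871 to 3110079) reached 82.9 ± 1.84 and 80.0 ± 3.78. The interval named for Gm13197 on chromosome 2 (5379223 to 5379378), within Camk1d in the reference, reached 63.3 ± 10.05 and 60.6 ± 3.27. Gm23935 on chromosome 16 (11143977 to 11144286), at the start of a microRNA-type transcript and within Zc3h7a in the reference, reached 49.3 ± 16.3 and 55.1 ± 4.53. Filip1l (intron 1), Gm2651, Mir6356 and Gm33838 were also among the 10 highest of both groups, with mean fold enrichment over the 6 libraries of 51.4, 51.2, 51.0 and 49.9. The last of the 10 was Gm27940 in flox controls (43.6) and Gm25352 in Armc5 KO (45.6). The other 9 names were common to the 10 highest of both groups.

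Many of the intervals sat in dense groups. Taking 3 or more intervals with gaps of at most 100 kb as a group, 8 groups held 53 intervals (51.0%). The largest held 17 intervals between 3000005 and 3038215 on chromosome 9, at Gm10722, Gm11168, Gm10715, Gm10717, Gm10718, Gm10719, Gm10720, Gm17535 and Mir101c. A further 12 lay between 3148598 and 3199875 on chromosome 11, 9 of them named for Sfi1, which encodes a centrosome protein. The group on chromosome 17 from 39843039 to 39848787 covered annotated ribosomal RNA transcripts, with a mean background of 130 fragments and mean fold enrichment per interval of 2.27 to 3.05. Of all 104 intervals, 35 were intergenic (33.7%, Clopper-Pearson 95% interval 24.7 to 43.6%), 29 in introns, 22 at promoters, 11 at transcription end sites and 7 in exons. Mean shares per library differed between groups by at most 1.497 percentage points. Intergenic intervals made up 34.3 ± 2.11% in flox controls and 35.1 ± 0.345% in Armc5 KO (exact permutation p = 0.8, adjusted over 5 classes 1.0). Promoter intervals made up 21.1 ± 0.69% and 19.8 ± 1.33% (SD, n = 3 each; exact permutation p = 0.3, adjusted p = 0.75). The smallest p that 3 against 3 samples allow is 0.1.

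Flox controls and Armc5 KO had similar numbers of called intervals. Flox controls 1, 2 and 3 had 94, 97 and 64, a mean of 85.0 ± 18.2, and Armc5 KO 1, 2 and 3 had 85, 88 and 75, a mean of 82.7 ± 6.81 (SD, n = 3 each). The difference of -2.33 intervals was smaller than the spread between replicates (exact two-sided permutation p = 0.9, with 0.1 the smallest possible). Its sign rested on single libraries: it was -12.8 without flox control 3, and 2.17, 3.67 and 1.5 without flox control 1, flox control 2 and Armc5 KO 3. Flox control 3 stood apart from the other 5 libraries. Its narrowest peak was 112 bp, against 86 to 88 bp in the others. Its summit pileup ranged from 0.217 to 4.48 times the mean of flox controls 1 and 2 over the 55 common intervals. The 3 intervals at Gm10800 and Gm10801 on chromosome 2 held 36.0% of its summed pileup, against 15.8 to 19.1% in the other libraries.

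**Figure D2:**
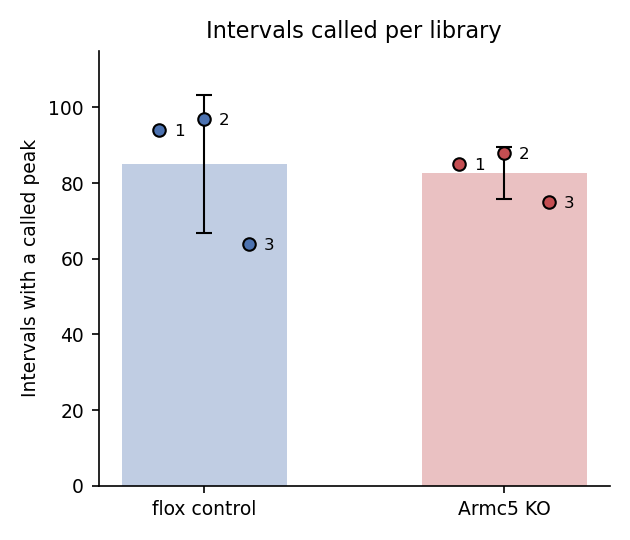
Number of intervals with a called peak (y axis) in flox control and Armc5 KO libraries (x axis), with bars for the mean of 3 libraries, error bars for the SD and numbered points for replicates. The groups overlap, with means of 85.0 and 82.7, and flox control 3 is the lowest library at 64.

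**Figure D3:**
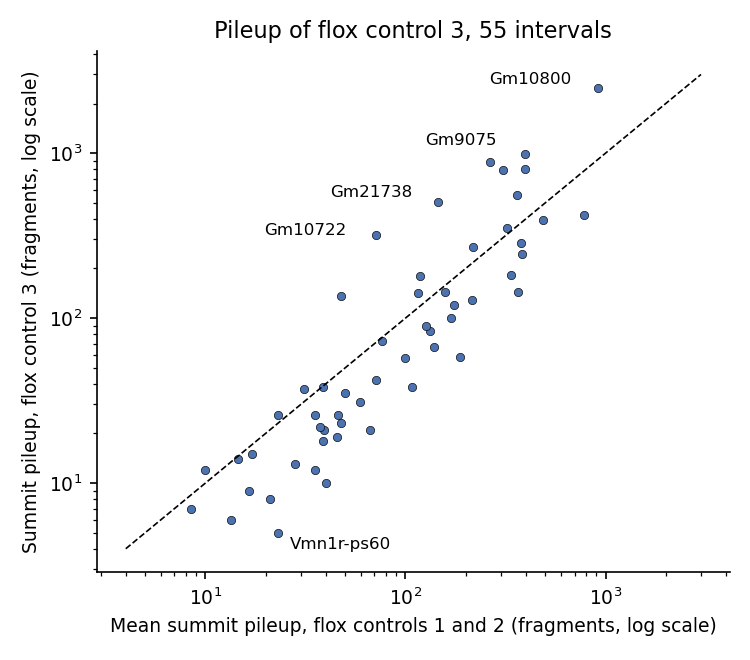
Summit pileup in flox control 3 (y axis, fragments, log scale) against the mean of flox controls 1 and 2 (x axis, fragments, log scale), 1 point per interval called in all 6 libraries, with the dashed line at equal pileup. Of 55 intervals 16 lie above the line, up to 4.48 times at Gm10722, and the lowest, Vmn1r-ps60, is at 0.217 times.

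Most intervals were found in both groups. Of 104, 92 (88.5%) had a peak in at least 1 library of each group, 9 in flox controls only and 3 in Armc5 KO only. The flox-only count rested on single libraries, being 5 without flox control 2 and 14 without Armc5 KO 2. The 12 intervals found in 1 group only compared with 9 to 13 found on 1 side only in the 9 other splits of the libraries into 3 and 3. None was called in all 3 libraries of 1 group and 0 of the other. The flox-only intervals with the highest fold enrichment were at Gm9758 on chromosome 5 (14914956 to 14915102, promoter, 11.1 in flox controls 1 and 2), Gm50357 on chromosome 19 (8.97, flox control 2) and Gm43391 on chromosome 5 (7.88, flox control 2). The others were at Tmem267 (7.14 and 5.80), Gm21738 (7.05), Gm11168 (6.87), Eif4enif1 (4.01) and Sfi1 (3.63), and those at Gm11168 and Sfi1 were called in 2 flox controls each. The Armc5 KO-only intervals were at Gm10720 on chromosome 9 (3015695 to 3015810, 12.5, Armc5 KO 3), Gm23939 on chromosome 1 (4.76, Armc5 KO 1 and 2) and Fau-ps2 on chromosome 11 (3.11, Armc5 KO 2).

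No interval passed the test for a difference in fold enrichment between Armc5 KO and flox control. The 55 intervals called in all 6 libraries were not 55 separate loci. The dense group on chromosome 9 held 10 of them. The groups on chromosome 11, at Gm21738 and at ribosomal RNA transcripts held 4 each. Among the 55, limma called 0 at an adjusted p of 0.05, and 1 had an unadjusted p under 0.05. That interval was at the promoter of Gm10719 on chromosome 9 (3018320 to 3018688), in the group of 17 named above. Its fold enrichment was 14.5 ± 1.73 in flox controls and 7.73 ± 3.39 in Armc5 KO (SD, n = 3 each). The log2 difference was -0.89 (SE 0.28, 95% interval -1.53 to -0.24, adjusted p = 0.742 with limma). All 3 Armc5 KO values (5.64, 5.90 and 11.6) lay below all 3 flox values (14.9, 12.6 and 16.0). Chance separates 3 values from 3, in either direction, in 10% of such comparisons, and this interval had the smallest p of 55. Values were separated in the same direction at Cdk8 and Muc3, and in the opposite direction at 1 CT010467.2 interval. Without Armc5 KO 3 the Gm10719 interval passed adjustment (log2 difference -1.19, adjusted p = 0.0429 with limma). It also passed with the replicate number as a block, a pairing that the labels do not state (adjusted p = 0.00205 with limma). In Armc5 KO 1 and 2 its peak was 122 and 123 bp wide, against 355 to 365 bp in the other 4 libraries. The folds came from different positions: the summit lay between 3018355 and 3018365 in flox controls 1 and 2 and Armc5 KO 3, and between 3018590 and 3018648 in flox control 3 and Armc5 KO 1 and 2. Over the 55 intervals the median log2 difference was -0.05, and 37 were lower in Armc5 KO. This tally moved with the scale and with single libraries: 25 were lower with the local ratio of pileup to background, 42 with median-centred fold, 26 without flox control 2 and 46 without flox control 3. The 95% interval reached a median of 0.44 to either side of the difference on the log2 scale. These folds were set within each library, and a difference in depth can move them.

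**Figure D4:**
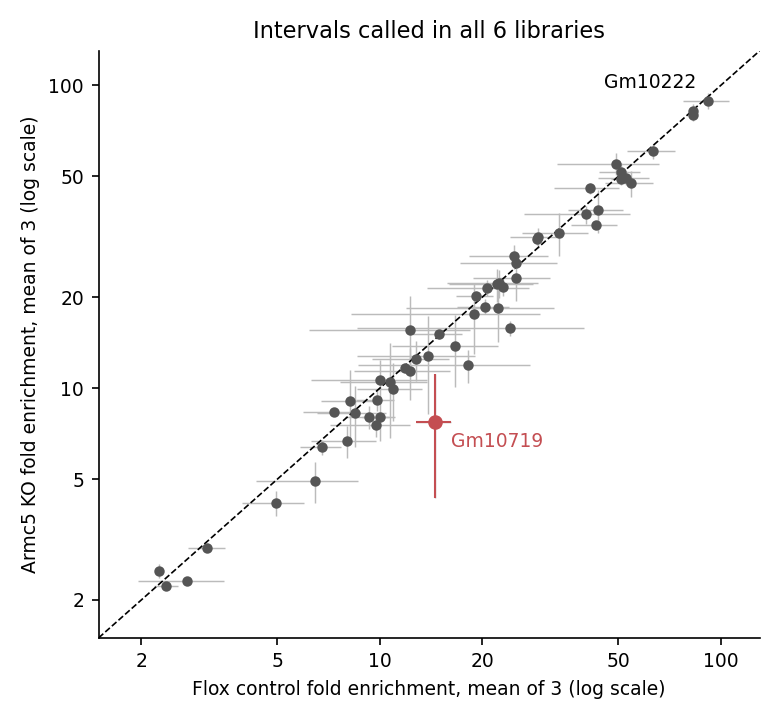
Mean fold enrichment in Armc5 KO (y axis, log scale) against flox control (x axis, log scale) for the 55 intervals called in all 6 libraries, with error bars for the SD of 3 libraries and the dashed line at equal fold. Points follow the line from Gm10222 (91.7 and 88.8) downward, and Gm10719 lies lowest beneath it (14.5 and 7.73).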

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

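The tests on local ratio, centring, summits, peak width, averaged libraries, presence in at least 2 libraries, peaks in place of intervals and 100 kb distance, and leaving out each library for shared intervals, annotation classes and the fold of the most enriched intervals, were chosen after the data were seen. The count of changed intervals stayed 0 with limma for both other pseudocounts, without the low-value filter, with the local ratio, centred pileup or fold, and averaged Armc5 KO 1 and 2. It was also 0 among the 30 intervals with nearby summits, which leave out Gm10719. It ranged from 0 to 1 when each library was left out, the 1 being Gm10719 without Armc5 KO 3. The replicate number as a block gave 1 call, Gm10719 (adjusted p = 0.00205), while its adjusted p otherwise ranged from 0.0429 to 0.985. Whether the numbers pair the samples stays unsettled: deviations of same-numbered libraries correlated at 0.0258, 0.605 and 0.276 across intervals. By correlation of the fold, flox controls 2 and 3 were closest to the Armc5 KO library of their own number (0.9856 and 0.9179) and flox control 1 to Armc5 KO 3 (0.9845), while by pileup flox control 1 was closest to Armc5 KO 1. The median log2 difference was -0.05 with the fold, -0.09 with the centred fold, 0.02 with the local ratio and 0.08 with the centred pileup. The difference in intervals per library ranged from -12.8 to 3.67 when each library was left out, and turned positive in 3 of these 6 settings. With the most enriched intervals alone, 50 were shared, since fewer were counted. Intergenic intervals were 44.8% with 1 interval per gene, because dense groups then count once per name. Within 100 kb lay 6 list genes in place of 0. For these comparisons 39 other alternatives were tried. Each kept direction and side of the threshold or stayed within 1.5 times the count or the interval of the share. Some could not have changed and say nothing about stability. The low-value filter removed no interval, and subsets of 0 named list genes stay at 0. The permutation tests of interval numbers allow no p under 0.1. The count tests listed as alternatives were not run, since the table holds no counts. The lowest pileup of a called peak was 3 to 6 fragments per library, so the weakest peaks carry a large counting error.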

Other observations

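The tests of depth alone, of coverage and of intervals shared by libraries, and the count over splits, were chosen after their results were seen. The tests of peak length and of the added 1 were written down before theirs.

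The intervals crowded the starts of the chromosomes. Of 104 intervals, 35 (33.7%) began within 4 Mb of position 0, where 302 of 20661 autosomal protein-coding reference genes (1.46%) begin. They lay on 8 chromosomes, 17 of them on chromosome 9 and 12 on chromosome 11. An interval of 111 bp on chromosome 1 (78573996 to 78574106), chosen after its values were seen, was named for 5730419F03Rik, while the reference places Mogat1, which encodes a monoacylglycerol acyltransferase, over it. It was called in flox control 2 (fold enrichment 6.65, pileup 6) and Armc5 KO 2 (7.36, pileup 7).

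Flox control 3 had the fewest intervals (64). Lower depth alone is argued against, because its pileups did not keep 1 ratio to those of flox controls 1 and 2 (chi-square per degree of freedom 62.9). By single pairs this value was 37.3 with flox control 1 and 54.7 with flox control 2, against 3.09 between flox controls 1 and 2. A longer minimum peak length remains a candidate explanation for the count. With peaks under 112 bp left out of every library, flox control 3 kept 64 intervals and the other 5 had 62 to 84. That limit is the narrowest peak of flox control 3, so only the other libraries could lose intervals by it. Of the 40 intervals missing in flox control 3, 12 had only narrower peaks in the other libraries, and 28 had a wide enough peak there. The 40 also had a lower median pileup there than the intervals called in flox control 3 (17.5 against 49 fragments), so weak signal stays open for them. Its uneven pileups, a wrong label and a difference between mice were not tested.

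The table was short and named none of the list genes. Low coverage is a candidate explanation: the lowest background at a peak was 0.035 to 0.0868 fragments per base, where a peak at each library's own lowest called significance needs at least 46.1 times the background (46.1 to 85.7 over libraries). A rule that keeps only intervals shared by libraries is argued against, since 8 intervals were called in 1 library. Whether the intervals lie in sequence with many copies in the genome, and whether reads or peaks were filtered before deposit, were not tested. Mean local background over common intervals was 130 fragments in the dense group at ribosomal RNA transcripts and 54.2 in that at Gm10800 and Gm10801. It was 0.379 to 8.33 in the other dense groups with common intervals. No biological explanation was tested.

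The 10 splits of the 6 libraries into 3 and 3 all gave 0 intervals with limma. Thus 10 of 10 were as high as the real split (0, highest other 0), which a real count of 0 fixes in advance. This count therefore cannot decide, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05, the real split gave 1 interval and the others up to 13, which points to a structure of the samples. The split with 13 set flox controls 1 and 2 and Armc5 KO 2, the 3 libraries with the highest median pileup, against the rest. Flox control 3 had the highest summed pileup over the same intervals (11562, against 9624 in flox control 2). Of its sum, however, 36.0% lay in the 3 intervals at Gm10800 and Gm10801, so the sum is a poor measure of depth. A candidate explanation is that the 1 added to pileup and background makes the fold depend on depth: with the local ratio without the added 1, the same split gave 2 intervals with p under 0.05, 1 of them past adjustment (adjusted p = 0.0277). The median log2 difference between deeper and shallower libraries was 0.41 for 20 intervals with a mean background under 1 and 0.05 for the other 35 with the fold, and -0.02 and -0.03 with the local ratio. Libraries were ranked as deeper by the pileup of the same summits that enters the fold. These differences are therefore partly set by that choice and are no independent evidence of a depth effect.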
